A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

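The series holds 24 libraries of the yeast Saccharomyces cerevisiae (CEN.PK background), of which 12 are RNA-seq and 12 are ribosome profiling. Strains carrying wild-type DIM1 (WT) or the alleles E85Q or D87E were sampled in medium with methionine and again after 2 h without sulfur, and per the labels each genotype is represented by 2 numbered strains, called isolates here (WT 172 and 600, E85Q 623 and 625, D87E 887 and 888). This gives 6 groups of 2 samples per assay. According to the labels, the RNA-seq libraries were made from rRNA-depleted total RNA with strand information, the matched libraries of both assays came from the same sample, reads were 50 bases long, and footprint libraries were pooled after the ligation of barcoded linkers whenever possible.

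The deposited values are RPKM, reads per kilobase of gene and 1e6 reads, which the authors computed for each library, with footprints of 18 to 34 nt counted for ribosome profiling. The submitters' processing notes name Bowtie 1.1.2, TopHat2 2.1.1 and the sacCer3 build with no role given. The names of both tables say that positions were masked. Neither the masked positions nor which reads enter the scaling are stated. Each table has 7133 entries, of which 829, among them the tRNA, snoRNA and rRNA entries, carry no value and 6304 carry values; 588 of those with values had no match in the reference annotation.

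Low RPKM values of many genes were multiples of a single step in each library, from which the reads behind the scaling were recovered. They numbered 24.3 to 32.3 M (1e6) for RNA-seq and 21.4 to 81.4 M for footprints. Of the genes whose step gave a depth, 272 of 485 in RNA-seq and 257 of 462 in footprints lay on the fitted line. The recovery assumes that 33 bases of each gene were left out, a fitted value; 74.2% of the footprint values and 77.7% of the RNA-seq values of up to 20 reads then lay within 0.05 of a whole read. On simulated data the recovered depth differed from the true depth by at most 4.76e-05%. At these depths 3 reads in a 1-kb gene correspond to an RPKM of 0.037 to 0.14, which covers counting error only. Read numbers were used in checks and in an alternative fit, and no step of the main test rests on them.

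Values were transformed as log2(RPKM + 1) without further scaling, and translational efficiency (TE) was taken in each sample as the log2 footprint value minus the log2 RNA-seq value. Genes with a mean RPKM of at least 5 over the libraries of both assays were tested, 4888 in all; 8 of them are marked dubious in the tables, 80 overlap another protein-coding gene and 7 are absent from the reference. For each assay and for TE, limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend) was fitted to the means of the 6 groups, which share a pooled estimate of the spread, and the 10 comparisons were tested two-sided. Benjamini-Hochberg adjustment ran over all genes within a comparison, and a gene was called at an adjusted p below 0.05. The comparisons were starvation (without minus with methionine) in each strain, each mutant against WT in each medium, and the pairwise differences between the starvation responses of the strains. Values are given with the standard error (SE) of the fit or the standard deviation (SD) of the samples, with n = 2 per group throughout. Tables were handled and plots drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

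Comparisons, tests, gene lists, the naming rule and all alternatives except those listed as added later were fixed before the data were examined. The 29 gene lists cover sulfate assimilation and methionine synthesis; methionine and sulfur-compound transport and salvage; cysteine, S-adenosylmethionine (SAM) and glutathione metabolism; sulfur pathway regulators; general amino acid control (Gcn4) biosynthesis genes; one-carbon and folate metabolism; purine synthesis; cytosolic ribosomal proteins; 18S rRNA maturation and small-subunit assembly; 60S subunit assembly and RNA polymerase I. They also cover translation initiation factors, elongation and termination factors, cytosolic aminoacyl-tRNA synthetases, glycolysis and fermentation, low-sulfur isozymes and their partners, the respiratory chain and TCA cycle, environmental stress response (Msn2/Msn4) genes, cytosolic chaperones, oxidative defence (thioredoxin, peroxiredoxin), autophagy and the proteasome. The remainder are phospholipid and inositol synthesis, the iron regulon, thiamine and biotin synthesis, histones, and 4 sets for checks of mating type, ploidy and marker genes (a-cell, alpha-cell, haploid-specific and auxotrophic marker genes). Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison and measure, and again with the correlation estimated from the data; list medians are given relative to the median of all tested genes.

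The naming rule takes DIM1 always. In each starvation comparison and measure it takes the 10 largest rises and 10 largest falls among called genes that changed the same way in both isolates. In the other comparisons it takes the 5 largest rises and 5 largest falls among called genes, where for a mutant against WT both mutant samples had to lie outside the range of both WT samples. From each list described, it takes the 4 members with the smallest adjusted p. Which lists the report describes for each comparison was chosen after their results were seen, and the remaining lists are given for starvation in WT at the end, with the sets for checks of strains also given for E85Q against WT with methionine. Genes named outside the rule are marked as chosen after their values were seen.

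The alternatives were a pseudocount of 0.1 or 10, no filter or a mean RPKM of at least 50, median-centring of each library, an isolate block, an unpaired footprint-to-mRNA ratio, an estimated inter-gene correlation, and leaving out each library in turn. Added after seeing the data were voom precision weights on recovered reads, a subtraction of carried-over footprints, and a crossed isolate block. The subtraction took, per isolate, the smallest footprint ratio with to without methionine among the 20 genes with the largest mRNA rise. That fraction of the library without methionine was subtracted from the library with methionine of the same isolate. It assumes that all footprints with methionine of the gene with the smallest ratio were carried over, which was not tested. The correlation across genes of an isolate's deviations in both media was -0.18, 0.17 and -0.05 for mRNA in WT, E85Q and D87E, -0.02, 0.41 and 0.05 for footprints, and -0.02, 0.37 and -0.04 for TE; the WT mRNA value led to the crossed block. No library was left out of the main test.

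The procedure was tested on simulated data with 2 samples per group, in which 67, 67 and 66 of 4888 genes changed 1.5-, 2- and 4-fold. Values were independent normal draws around 1 mean per gene shared by all groups, with the residual spread of the real data. Shifts of whole libraries, correlation between genes and changes in most genes were not simulated. The rates below are therefore not error rates of the real comparisons. For a mutant against WT in medium with methionine, mRNA calls recovered 86.6%, 98.5% and 100% of these with 13 false calls, footprints 80.6%, 92.5% and 100% with 7, and TE 77.6%, 92.5% and 100% with 9. For a difference of starvation responses, mRNA recovered 68.7%, 98.5% and 100% with 12 false calls, footprints 58.2%, 86.6% and 100% with 4, and TE 56.7%, 86.6% and 100% with 7.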

Results

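Ribosome footprints and mRNA were measured in yeast with wild-type Dim1 (WT) or the Dim1 variants E85Q and D87E, growing with 1 mM methionine or starved for 2 h in sulfur-free medium. Dim1 is the enzyme that dimethylates adenosines near the 3′ end of 18S rRNA. The title of the series poses the question that the comparisons address, whether translation responds to sulfur supply by way of this rRNA methylation. Each of the 6 groups (3 genotypes, with or without methionine) held 2 samples from different isolates, and each sample gave an mRNA and a footprint library. The recovered reads behind the mRNA values numbered 24.3 to 32.3 M (1e6) per library. Behind the footprint values with methionine stood 53.6 and 57.6 M reads in WT isolates 172 and 600, 49.1 and 52.6 M in E85Q 623 and 625, and 66.3 and 81.4 M in D87E 887 and 888. The footprint libraries without methionine were shallower, at 22.3 and 24.6 M in WT, 39.2 and 47 M in E85Q and 21.4 and 27.3 M in D87E. Within groups, the median SD per gene was 0.034 to 0.10 on the log2 scale, and the correlation between isolates across the 4888 tested genes was 0.986 to 0.999 for mRNA and footprints and 0.966 to 0.978 for their ratio, the translational efficiency (TE). Genes are not independent replicates.

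DIM1 itself (YPL266W, chromosome XVI, 39121 to 40077) was expressed in all strains. Its mRNA stood at 77.7 ± 0.41 RPKM (SD, n = 2) in WT, 91.7 ± 0.58 in E85Q and 82.1 ± 3.22 in D87E with methionine, and at 16.6 ± 0.32, 17.4 ± 0.33 and 16.9 ± 1.61 without. On starvation DIM1 mRNA changed by -2.16, -2.33 and -2.21 on the log2 scale in WT, E85Q and D87E (SE 0.06 each, adjusted p = 4.5e-10, 2.9e-10 and 3.8e-10), and its footprints by -1.80, -2.35 and -1.98 (SE 0.12, adjusted p = 2.6e-07, 5.3e-08 and 1.3e-07). DIM1 mRNA was 0.24 (SE 0.06) higher in E85Q than in WT with methionine (adjusted p = 0.023), a call lost when any of the 4 libraries was left out and on median-centring, which gave 0.11.

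Starvation of WT cells asks which genes respond to the loss of sulfur when Dim1 is intact. The sulfate permease genes SUL1 and SUL2 rose by 9.89 (SE 0.08) and 8.28 (SE 0.07) in log2 mRNA. SUL1 went from 2.01 ± 0.15 to 2851 ± 140.4 RPKM. MET3, which encodes ATP sulfurylase, rose by 8.32 (SE 0.07) and MET2, for homoserine acetylation, by 8.46 (SE 0.07). Of the 16 genes of sulfate assimilation and methionine synthesis 15 rose and 1 fell, and the list median was 5.76 above that of all genes. The 17 genes of cysteine, SAM and glutathione metabolism had 14 rises and 2 falls (relative median 2.5). The oligopeptide transporter gene OPT1 rose by 8.22 (SE 0.07), STR3 by 7.84 (SE 0.08), DUG3 by 5.29 (SE 0.07) and GSH1, the first enzyme of glutathione synthesis, by 3.77 (SE 0.05). Among the 10 largest rises stood genes for the use of other sulfur sources: JLP1 for sulfonate breakdown (10.14, SE 0.14), the S-methylmethionine permease gene MMP1 (9.32, SE 0.10), the cysteine transporter gene YCT1 (8.91, SE 0.08), YIL166C (9.07, SE 0.22) and the permease gene AGP3 (8.57, SE 0.08). The list of sulfur-compound transport and salvage held both rises and falls and did not pass as a list. The largest rise was that of PDC6, a minor pyruvate decarboxylase gene, by 10.32 (SE 0.17). The adjusted p values of these genes lay between 3.7e-14 and 1.1e-10.

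Genes of iron uptake, stress defence and autophagy rose as well in starved WT cells. All 21 measured iron regulon genes rose (relative median 2.40), among them the cell wall protein genes FIT2 by 6.78 (SE 0.11) and FIT3 by 6.42 (SE 0.13) and the mRNA decay factor TIS11 by 6.28 (SE 0.13). All 27 measured autophagy genes rose (relative median 1.49), with ATG1 up by 2.75 (SE 0.06) and ATG8 by 2.57 (SE 0.09). Of the environmental stress genes 31 of 31 rose (relative median 1.94), such as SOL4 by 3.64 (SE 0.15) and the trehalase gene NTH1 by 1.66 (SE 0.07). These counts were the same when adjusted over the list alone. The camera adjusted p was 9.8e-06 for sulfate assimilation, 0.0066 for cysteine and glutathione metabolism, 4e-06 for iron, 1.4e-05 for autophagy and 6.5e-05 for stress genes. With an estimated correlation none of these calls held, at adjusted p = 0.137 to 0.479 with an estimated correlation.

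The machinery of protein synthesis fell in WT. Of 126 cytosolic ribosomal protein genes 125 lost mRNA and 1 gained, with a list median of -4.53 relative to all genes. Examples were RPS25B (-3.35, SE 0.10), RPL19A (-3.54, SE 0.11), RPL9A (-5.50, SE 0.24) and RPS26B (-5.46, SE 0.24). Ribosomal protein genes made up 29.2% and 30.7% of summed mRNA RPKM in the WT libraries with methionine and 2.30% and 2.05% without. The 45 genes of 60S assembly and RNA polymerase I had 44 falls (relative median -3.23) and the 46 of 18S rRNA maturation and small-subunit assembly 45 (-2.70), with 1 rise in each. Among them were NOG1 (-3.53, SE 0.09), RPA190 (-3.50, SE 0.09) and RRP5 (-3.78, SE 0.08). All 20 aminoacyl-tRNA synthetase genes fell (-1.96), as did 24 of 26 initiation factor genes (-1.68, 1 rise), with GLN4 at -1.59 (SE 0.06) and the eIF3 subunit gene NIP1 at -2.22 (SE 0.07). The nucleolar protein gene NSR1 had the largest fall (-5.94, SE 0.16), from 241 ± 11.1 to 2.96 ± 0.52 RPKM, and the ribosome-associated chaperone gene SSB1 fell by 5.22 (SE 0.29). RPL4A, which the naming rule selects, was listed at 0 in both WT mRNA libraries without methionine, against 54.5 ± 50.8 RPKM with it. The camera adjusted p of these lists ran from 1.3e-39 to 1.3e-11, and it was adjusted p = 0.215 to 0.278 with an estimated correlation.

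Several lists split. Of 44 amino acid biosynthesis genes under Gcn4, the activator of the general amino acid response, 32 fell and 7 rose (relative median -1.19). The rises included the serine and homoserine pathway genes SER33 (4.99, SE 0.07), SER1 (1.47, SE 0.07) and HOM3 (2.08, SE 0.09), while SER3 fell by 1.85 (SE 0.09). Respiratory chain and TCA cycle genes had 33 falls and 4 rises among 44 (-0.88), with aconitase ACO1 at -2.01 (SE 0.08) and SDH2 at -1.48 (SE 0.08). Glycolysis and fermentation genes had 14 falls and 7 rises among 21 (-1.11): HXK2 stood at -1.56 (SE 0.07), ADH1 at -2.20 (SE 0.10) and TDH2 at -2.56 (SE 0.12). The camera adjusted p was 5.1e-07, 4.6e-08 and 0.0021, or adjusted p = 0.479, 0.310 and 0.310 with an estimated correlation, and the glycolysis call was lost on median-centring. In all, 4246 of 4888 genes passed in WT mRNA, 2943 up and 1303 down, with 1721 changed at least 2-fold (1099 up, 622 down). The median gene rose by 0.40 (log2), so that centring the libraries gave 1973 up and 2025 down and turned the direction of 159 genes.

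**Figure D1:**
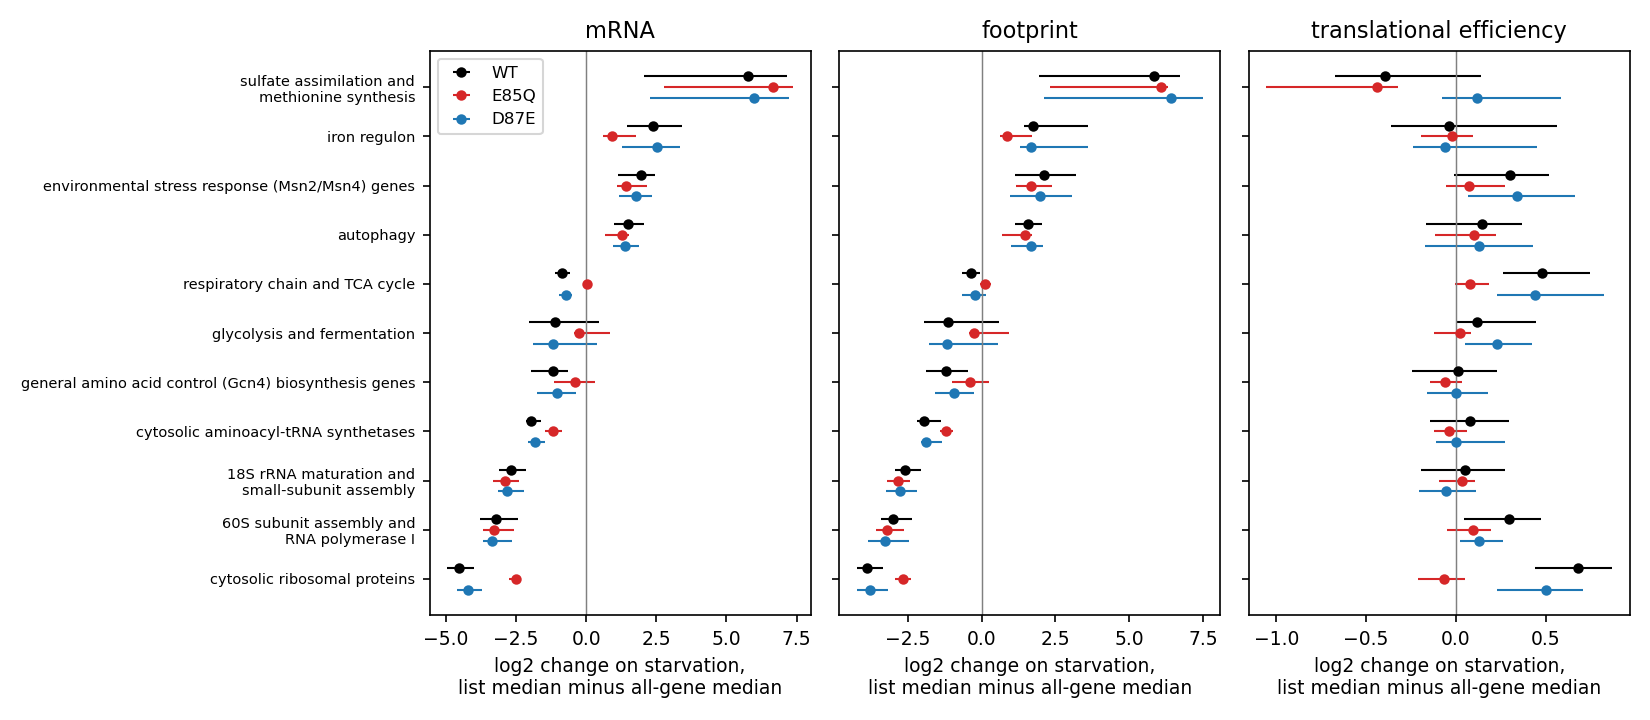
Change of 11 gene lists on starvation (log2, horizontal axes) in mRNA, footprints and translational efficiency, each shown as the list median minus the median of all tested genes with bars over the quartiles of the list, for WT, E85Q and D87E. The ribosomal protein list stood at -4.53 in WT, -2.5 in E85Q and -4.23 in D87E for mRNA, while the 60S assembly list stood at -3.23, -3.31 and -3.36.

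Footprints in starved WT cells followed most of these groups. The largest falls were those of NSR1 (-5.19, SE 0.32), RPL9A (-5.03, SE 0.36), the IMP dehydrogenase gene IMD4 (-4.86, SE 0.20) and SSB1 (-4.71, SE 0.24). Ribosomal protein genes had 125 falls and 1 rise (relative median -3.90), 60S assembly 44 and 1 (-3.01), and small-subunit assembly 44 falls, 45 when adjusted over the list alone (-2.58). PDC6 rose by 7.86 (SE 0.35), YCT1 by 7.82 (SE 0.36), FIT3 by 7.82 (SE 0.37), JLP1 by 7.79 (SE 0.33) and SUL1 by 7.67 (SE 0.43). Sulfate assimilation genes had 15 rises and 1 fall (5.83), iron genes 21 rises (1.73), autophagy 26 of 27 (1.56) and stress genes 30 of 31 (2.13), and Gcn4 biosynthesis genes had 31 falls and 6 rises (-1.22). Camera gave adjusted p between 1.5e-28 and 3.3e-05, or adjusted p = 0.364 to 0.504 with an estimated correlation. In total 4078 genes passed, 2509 up and 1569 down; the median gene rose by 0.23, and after centring the split was 1988 up and 1980 down. Over the 20 genes with the largest mRNA rise, the median footprint value with methionine was 0.372% of that without in isolate 172 and 0.693% in isolate 600, against 0.229% and 0.207% for mRNA. Apart from the pseudocount, these ratios are the inverse of the rises, so a higher ratio means a smaller footprint rise.

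**Figure D2:**
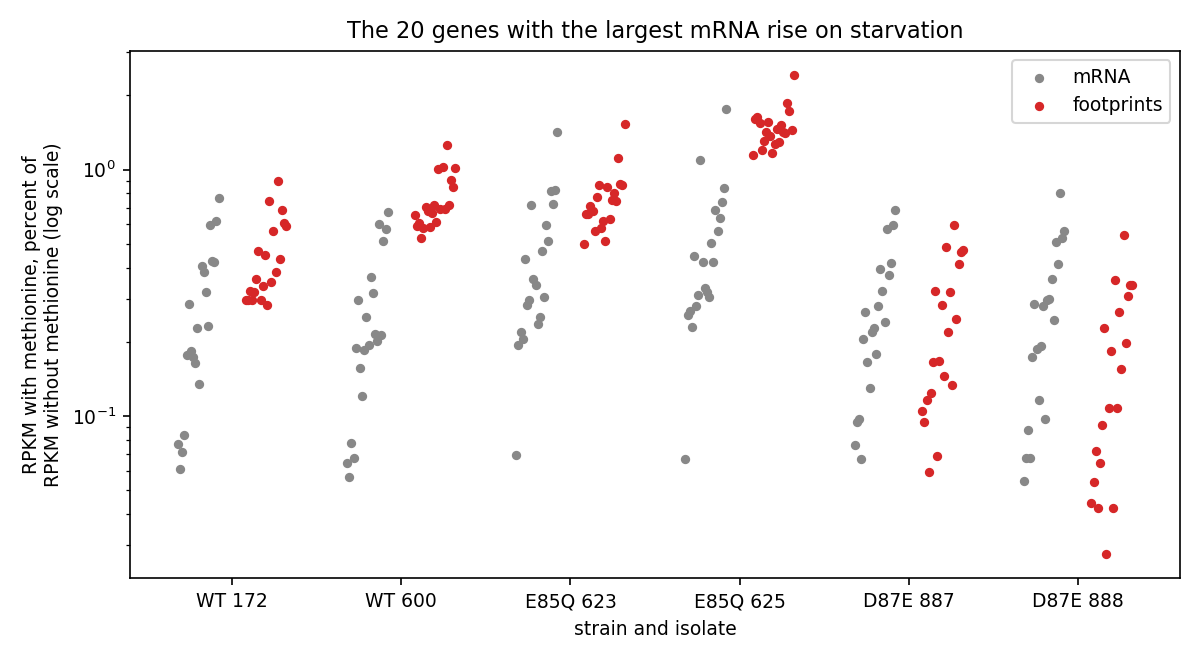
RPKM with methionine as a percent of RPKM without methionine (log scale) for the 20 genes with the largest mRNA rise, by strain and isolate, with dots for genes in mRNA (grey) and footprints (red). The lowest footprint ratio was 0.281% in WT 172, 0.527% in WT 600, 0.497% in E85Q 623, 1.15% in E85Q 625, 0.0593% in D87E 887 and 0.0276% in D87E 888, while that of mRNA was 0.0547% to 0.0695%.

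TE separated the groups in WT. Ribosomal protein genes gained TE as their mRNA fell: 66 of 126 rose and 4 fell, with a relative median of 0.68, and RPS26B rose by 1.35 (SE 0.12), RPL43B by 1.60 (SE 0.20) and RPS27A by 1.24 (SE 0.15). Respiratory genes had 29 rises and 1 fall (0.48), 29 and 2 adjusted over the list alone, such as the complex III subunit QCR7 by 0.96 (SE 0.09) and COX4 by 0.86 (SE 0.10). Histones had 8 rises among 10 (0.64), with HTB1 up by 0.92 (SE 0.10), and oxidative defence genes 15 rises and 2 falls among 23 (0.42), with HYR1 up by 0.74 (SE 0.10) and TRX2 by 0.60 (SE 0.10). Camera adjusted p was 1.3e-16, 8.1e-10, 0.00027 and 5e-05, or adjusted p = 0.351 to 0.646 with an estimated correlation. Sulfate assimilation genes had 1 rise and 8 falls and did not pass as a list (relative median -0.40, adjusted p = 0.29). DIM1 TE rose by 0.36 (SE 0.09, adjusted p = 0.0077), a call lost without WT 172 without methionine (0.29).

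Several single genes had large falls in TE in WT. JIP5 (YPR169W), for a nucleolar WD-repeat protein, stood at -5.31 in TE (SE 0.17, adjusted p = 1.2e-08): its mRNA went from 41.1 ± 2.46 to 107 ± 1.36 RPKM and its footprints from 28.2 ± 0.68 to 0.930 ± 0.48. The Mediator subunit gene SOH1 stood at -4.84 (SE 0.26), the helicase gene ECM32 at -3.29 (SE 0.11), SYG1 at -3.26 (SE 0.15) and CBP2, for mitochondrial splicing, at -3.01 (SE 0.13). In these genes mRNA rose and footprints fell. AAD6 (-4.85, SE 0.18) and RAD59 (-3.01, SE 0.08) fell in TE without a called fall in footprints: AAD6 footprints stood at 6.17 ± 0.59 RPKM with methionine and 7.40 ± 2.16 without, and RAD59 footprints at 6.50 ± 0.55 and 79.1 ± 0.47, while mRNA rose in both. GCN4, chosen after its values were seen, gained TE by 1.14 (SE 0.25, adjusted p = 0.0033), with 280 ± 19.5 footprint RPKM with methionine and 297 ± 17.7 without. The counts were 2603 genes, 816 up and 1787 down, around a median gene that fell by 0.12; centred, the split was 1432 up and 1033 down. In WT 178 genes rose in mRNA and fell in footprints, and 29 did the reverse (97 and 76 centred).

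Starvation of E85Q asks the same of cells with the first Dim1 variant. SUL1 mRNA rose by 9.80 (SE 0.08), MET3 by 8.37 (SE 0.07), STR3 by 8.11 (SE 0.08), JLP1 by 8.51 (SE 0.14), PDC6 by 8.42 (SE 0.17) and the methyltransferase gene MHT1 by 7.65 (SE 0.13). Sulfate assimilation genes had 15 rises among 16 (relative median 6.66; camera adjusted p = 2.3e-09), and this list passed also at adjusted p = 0.0303 with an estimated correlation. Cysteine and glutathione genes had 13 rises and 2 falls (2.14), iron genes 20 rises (0.92), autophagy 24 rises, 25 adjusted over the list alone (1.29), and stress genes 29 (1.43); TIS11 rose by 4.44 (SE 0.13), ATG1 by 1.99 (SE 0.06) and SOL4 by 3.20 (SE 0.15). Among the 10 largest falls were NSR1 (-5.80, SE 0.16), the CTP synthase gene URA7 (-4.92, SE 0.15), the RNA helicase gene DBP2 (-4.71, SE 0.11) and the RNA polymerase I gene RPA49 (-4.38, SE 0.11). The amino acid permease genes BAP2 (-4.54, SE 0.11) and DIP5 (-4.35, SE 0.05) also belonged to them.

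In E85Q 124 of 126 ribosomal protein genes fell in mRNA and 1 rose, with a relative median of -2.5; RPL19A stood at -2.26 (SE 0.11) and RPS25B at -2.35 (SE 0.10). Their share of summed mRNA RPKM went from 31.9% and 31.7% with methionine to 6.19% and 8.13% without. All 45 genes of 60S assembly fell (-3.31), 45 of 46 of small-subunit assembly (-2.89, 1 rise), all 20 synthetase genes (-1.20) and 25 of 26 initiation factors (-1.26, 1 rise), with NOP7 at -4.27 (SE 0.09) and TSR1 at -2.86 (SE 0.05). Camera gave these 5 lists adjusted p between 2.5e-25 and 3.5e-08, and cysteine and glutathione metabolism, iron, autophagy and stress genes 5.1e-05, 8.9e-06, 2e-06 and 2.5e-06; all 9 were at adjusted p = 0.213 to 0.480 with an estimated correlation. Gcn4 biosynthesis genes had 14 rises and 21 falls (-0.41, adjusted p = 0.1), respiratory genes 17 rises and 2 falls (0.04, adjusted p = 0.237; 15 and 2 adjusted over the list alone) and glycolytic genes 8 rises and 8 falls (-0.27, mean 0.62, adjusted p = 0.959), none of them called. Of 3757 genes that passed, 2274 rose and 1483 fell, 1057 of them at least 2-fold (443 up, 614 down), around a median gene 0.14 higher.

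E85Q footprints moved likewise: SUL1 rose by 6.96 (SE 0.43), MET3 by 6.84 (SE 0.38) and the sulfite reductase gene MET10 by 6.54 (SE 0.24), while NSR1 stood at -5.54 (SE 0.32), DIP5 at -4.57 (SE 0.11) and JIP5 at -4.47 (SE 0.14). Ribosomal protein genes had 123 falls and 1 rise (-2.67), 60S assembly 45 falls (-3.20), small-subunit assembly 45 (-2.83). Sulfate assimilation had 15 rises (6.09), iron 19 (0.85), autophagy 25 (1.46) and stress genes 29 rises and 1 fall (1.67), while Gcn4 genes had 11 rises and 19 falls (-0.40, adjusted p = 0.12, not called). Camera adjusted p of the called lists ran from 8.8e-25 for ribosomal proteins to 3.2e-05 for iron, or adjusted p = 0.312 to 0.549 with an estimated correlation. In all 3688 genes passed, 2192 up and 1496 down, around a median gene 0.13 higher. The median footprint ratio of the 20 most induced genes, with over without methionine, was 0.728% in isolate 623 and 1.43% in 625, against 0.349% and 0.423% in mRNA.

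Fewer genes were called in TE in E85Q (303) than in WT (2603), with 533 called in E85Q at pseudocount 10. GCN4 rose by 1.82 (SE 0.25, adjusted p = 0.0022), from 117 ± 0.59 to 276 ± 26 footprint RPKM while its mRNA went from 1183 ± 24 to 787 ± 15.5. The deaminase gene CHA1 rose by 1.38 (SE 0.11), the oligopeptide transporter gene OPT2 by 1.32 (SE 0.10) and PEX2 by 1.04 (SE 0.09). Negative changes were those of JIP5 (-4.57, SE 0.17), SOH1 (-3.50, SE 0.26), SYG1 (-3.05, SE 0.15) and RAD59 (-2.67, SE 0.08). Ribosomal protein genes had no rise and 4 falls (-0.07, adjusted p = 0.228), and no respiratory or oxidative defence gene passed (0.08 and 0.06, adjusted p = 0.056 and 0.390). No histone passed over all genes, and 3 rose adjusted over the list alone (0.19, adjusted p = 0.096). Sulfate assimilation genes had 9 falls, 10 adjusted over the list alone, with SUL1 at -2.84 (SE 0.41). The list stood at -0.44 (camera adjusted p = 3.8e-07, or adjusted p = 0.824 with an estimated correlation). After subtraction of carried-over footprints the list stood at 0.40 and SUL1 at 1.26. SUL1 itself set the ratio subtracted in E85Q 623 (0.497%) and 625 (1.145%). Its footprints with methionine were thus removed in full, and its value of 1.26 is no test. The 303 calls (94 up, 209 down; 184 and 166 centred) fell to 96 without E85Q 623 with methionine, 161 without 623 without methionine, 122 without 625 with and 120 without 625 without.

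D87E cells, with the second variant, gave starvation changes near those of WT. SUL1 mRNA rose by 9.94 (SE 0.08), PDC6 by 9.91 (SE 0.17), JLP1 by 9.85 (SE 0.14), MMP1 by 9.27 (SE 0.10) and MET2 by 8.42 (SE 0.07). NSR1 stood at -6.04 (SE 0.16), RPL9A at -5.11 (SE 0.24), RPS26B at -5.02 (SE 0.24) and URA7 at -4.78 (SE 0.15). Ribosomal protein genes had 124 falls and 1 rise (relative median -4.23), 60S assembly 44 and 1 (-3.36), small-subunit assembly 45 and 1 (-2.82), synthetases 20 falls (-1.84) and initiation factors 24 (-1.55). The share of ribosomal protein genes in summed mRNA RPKM went from 30.7% and 30.5% to 3.46% and 2.17%. Sulfate assimilation had 15 rises and 1 fall (5.99), cysteine and glutathione genes 14 and 2 (2.40), iron 21 rises (2.52), autophagy 27 (1.37) and stress genes 31 (1.78). Gcn4 genes had 10 rises and 27 falls (-1.05), respiratory genes 5 and 28 (-0.74), and glycolytic genes 7 and 14 (-1.19). All 13 lists passed camera, at adjusted p between 2.5e-39 and 0.0052, or adjusted p = 0.131 to 0.5 with an estimated correlation. In mRNA 4210 genes passed, 2965 up and 1245 down (1998 and 2016 centred, the median gene rose by 0.41), and 1699 changed at least 2-fold.

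D87E footprints showed 125 falls and 1 rise among ribosomal protein genes (-3.80), 44 and 1 in 60S assembly (-3.28) and 46 falls in small-subunit assembly (-2.77). Sulfate assimilation had 15 rises and 1 fall (6.42), iron 21 rises (1.68), autophagy 26 rises and 1 fall (1.66), stress genes 30 rises (1.99) and Gcn4 genes 6 rises and 28 falls (-0.92), with camera adjusted p from 7.9e-25 to 0.0011, or adjusted p = 0.430 to 0.615 with an estimated correlation. YIL166C footprints rose by 10.28 (SE 0.36), PDC6 by 10.18 (SE 0.35), FIT3 by 10.05 (SE 0.37) and JLP1 by 9.95 (SE 0.33); NSR1 stood at -6.38 (SE 0.32) and SSB1 at -5.47 (SE 0.24). The counts were 4024 genes, 2312 up and 1712 down (2005 and 1944 centred, median gene 0.15). In TE, ribosomal protein genes had 28 rises and 10 falls (0.50; 17 and 7 adjusted over the list alone), respiratory genes 22 and 4 (0.44; 21 and 3), histones 8 rises (0.89) and oxidative defence 12 and 3 (0.50). Camera gave adjusted p between 1.2e-10 and 1.1e-05, or adjusted p = 0.277 to 0.699 with an estimated correlation. Sulfate assimilation genes had 3 rises and 4 falls and did not pass (adjusted p = 0.317). JIP5 TE stood at -5.93 (SE 0.17), SOH1 at -4.58 (SE 0.26) and IRC7, a cysteine desulfhydrase gene, at -2.87 (SE 0.14), and LSO1 rose by 1.53 (SE 0.25). DIM1 TE rose by 0.23 (SE 0.09, adjusted p = 0.048), a call lost without D87E 887 in either medium or D87E 888 with methionine, at pseudocount 0.1, without a filter, with an isolate block, with an unpaired ratio and with voom. TE changed in 2979 genes, 639 up and 2340 down (1449 and 1146 centred), around a median gene that fell by 0.23; 277 genes rose in mRNA and fell in footprints and 13 did the reverse, against 11 and 3 in E85Q. On centring, counted after these values were seen, the numbers were 115 and 102 in D87E and 7 and 4 in E85Q, and the strains were not tested against each other in them.

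Across genes, the starvation changes of WT and D87E, from separate libraries, had a correlation of 0.993 with a slope of D87E on WT of 0.971 in mRNA, 0.990 and 1.04 in footprints and 0.886 and 0.918 in TE. For WT and E85Q these were 0.922 and 0.752 in mRNA, 0.931 and 0.790 in footprints and 0.571 and 0.326 in TE. In mRNA 3206 genes were called in the same direction in WT and E85Q and 199 in opposite directions.

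**Figure D3:**
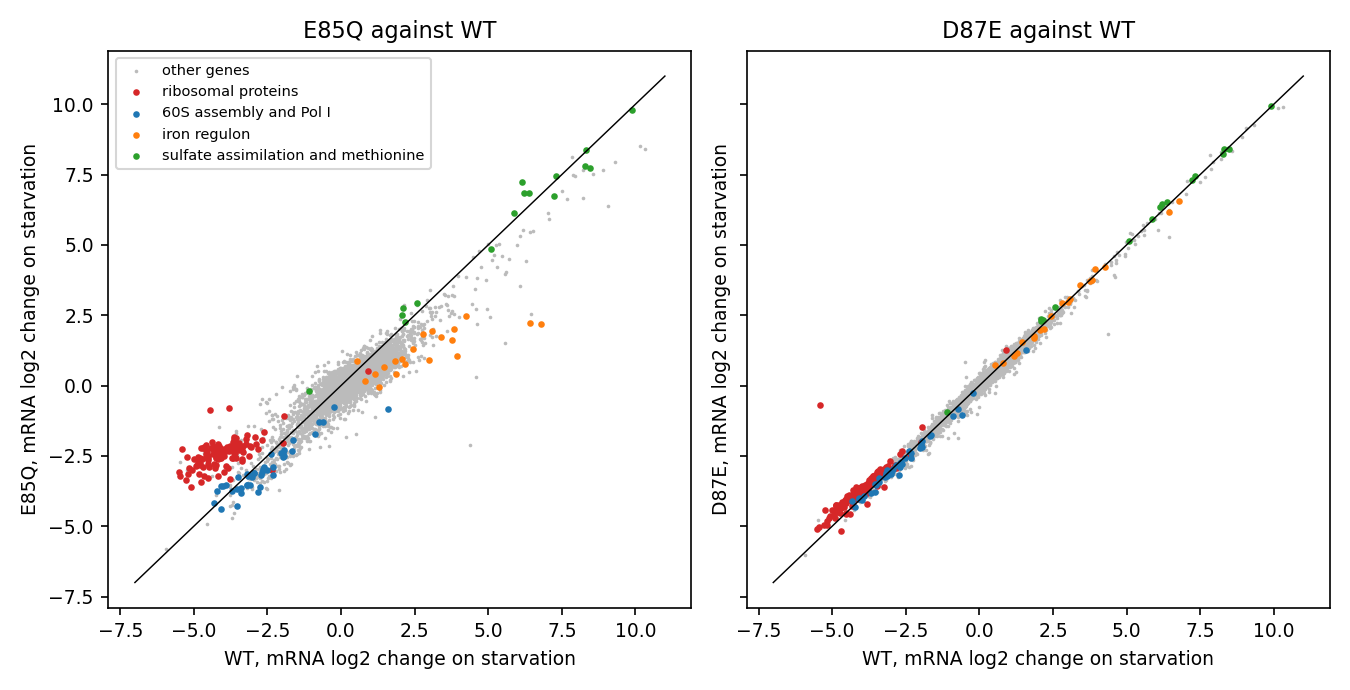
Log2 change of mRNA on starvation for each tested gene in WT (horizontal) against E85Q (left, vertical) or D87E (right, vertical), with 4 gene lists in colour and a line of equal change. Ribosomal protein genes (red) lay above the line in E85Q, with a median difference of 1.94 relative to all genes, and iron regulon genes (orange) below it, at -1.14.

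Comparing E85Q with WT in medium with methionine asks what the variant changes in growing cells. SNO1 and SNZ1, genes of vitamin B6 synthesis, were lower in E85Q in log2 mRNA (-1.30 and -1.19, SE 0.11, adjusted p = 0.00029 and 0.00046) and in footprints (-1.28 and -1.31, SE 0.13). Both belong to the Gcn4 list, of whose 44 members 33 fell and none rose in mRNA (36 adjusted over the list alone; relative median -0.66), and 21 fell and 1 rose in footprints (33 and 2; -0.58). The tryptophan synthase gene TRP5 fell by 0.80 (SE 0.11), and CPA1 footprints rose by 0.74 (SE 0.11). Iron genes had 12 falls and 2 rises in mRNA (12 and 3; -0.34) and 10 falls in footprints (11; -0.42), with the siderophore transporter gene SIT1 at -1.07 (SE 0.10) and -1.27 (SE 0.11) and TIS11 mRNA at -1.17 (SE 0.13). Glycolytic genes had 7 falls (8; -0.38), among them the phosphofructokinase genes PFK1 (-0.40, SE 0.06) and PFK2 (-0.40, SE 0.07). Small-subunit assembly had 23 rises (33; 0.17) and 60S assembly 19 (20; 0.16), with ENP1 up by 0.45 (SE 0.07) and RRN3 by 0.61 (SE 0.14). Bracketed counts are adjusted over the list alone. Camera adjusted p was 1.9e-28 and 3.4e-21 for Gcn4 genes in mRNA and footprints, 2.7e-08 and 1.8e-11 for iron, 7.4e-09, 3.4e-05 and 0.00084 for the others, or adjusted p = 0.211 to 0.702 with an estimated correlation.

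The ribosomal protein genes RPS9A (YPL081W, chromosome XVI, 404950 to 406044) and RPS22B were lower in E85Q with methionine in mRNA (-1.69, SE 0.25, and -1.5, SE 0.25), RPS9A changing from 398 ± 13.6 RPKM in WT to 123 ± 6.1. Footprints were lower by log2 values of -1.95 (SE 0.34) for RPS9A and -1.81 (SE 0.27) for RPS22B; both footprint calls were lost without WT 172 or WT 600, and RPS9A also without E85Q 623 or 625. The mating gene FUS1 rose in footprints by 1.02 (SE 0.10), and YMR090W in mRNA by 1.11 (SE 0.17). GCN4 footprints, chosen after their values were seen, stood at 280 ± 19.5 RPKM in WT and 117 ± 0.59 in E85Q (-1.26, SE 0.32, adjusted p = 0.042). COS1 mRNA was listed at 0 in both WT libraries and at 10.9 and 12.2 RPKM in E85Q 623 and 625. In mRNA 1396 genes passed, 1093 up and 303 down, 19 of them at least 2-fold; centring (the median gene rose by 0.11) gave 315 up and 670 down. The count was 366 without WT 600, 170 without E85Q 623 and 895 without E85Q 625. In footprints 372 passed, 199 up and 173 down (99 and 225 centred), and 40, 56, 47 and 89 without WT 172, WT 600, E85Q 623 and E85Q 625. FIT3 and FIT2 footprints stood at -2.60 (SE 0.37) and -1.86 (SE 0.29), the FIT2 call being lost without WT 600 or E85Q 625, and both after subtraction of carried-over footprints (0.044 and -0.69). In TE 7 genes passed, against 0 with an unpaired ratio, 1 without a filter, 2 at pseudocount 0.1 and 2 at pseudocount 10. Among the 7 were FIT3 at -2.12 (SE 0.30, adjusted p = 0.041), CHA1 at -1.07 (SE 0.11, adjusted p = 0.0079) and CPA1 at 0.59 (SE 0.09). FIT3 stood at 0.52 and was not called after subtraction, and it was not called without WT 600 or E85Q 625. The call of CHA1 was lost without WT 600, and that of CPA1 without WT 600, E85Q 623 or E85Q 625. The TE count was 20 without WT 172, 0 without WT 600 and 3 without E85Q 625, and no sulfate assimilation gene passed (3 adjusted over the list alone; 0.35, adjusted p = 1.2e-09, or adjusted p = 0.448 with an estimated correlation; -0.03 after subtraction of carried-over footprints).

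**Figure D4:**
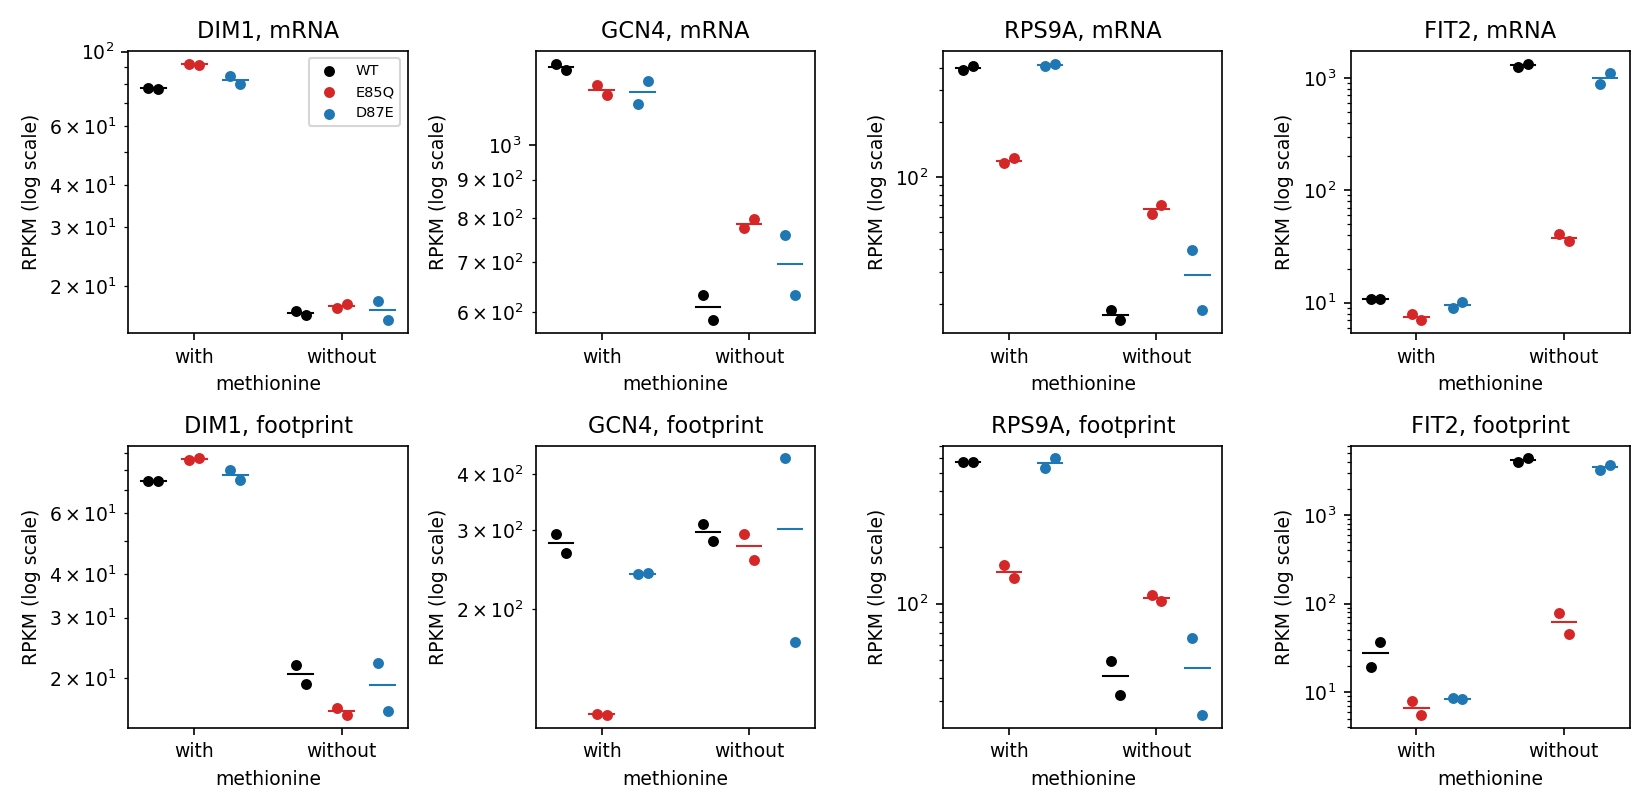
RPKM (log scale) of DIM1, GCN4, RPS9A and FIT2 in mRNA (upper panels) and footprints (lower panels) with and without methionine, with dots for the libraries and lines for the means of 2, by strain. RPS9A mRNA with methionine was 398 ± 13.6 in WT and 123 ± 6.1 in E85Q, and FIT2 mRNA without methionine was 1294 ± 64.1 in WT, 38.0 ± 3.9 in E85Q and 995 ± 152 in D87E.

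Without methionine, the same comparison asks what the variant changes in starved cells. FIT2 mRNA was lower in E85Q, at 38.0 ± 3.9 RPKM against 1294 ± 64.1 in WT (-5.06, SE 0.11, adjusted p = 2.9e-09), as was FIT3 (-4.69, SE 0.13), the ferric reductase gene FRE5 (-4.11, SE 0.19), the hydrophilin gene GRE1 (-4.25, SE 0.56) and LSO1 (-3.90, SE 0.36). Of 21 iron genes 20 fell and 1 rose in mRNA (relative median -1.40), and 20 fell in footprints (21 adjusted over the list alone; -1.26), where FIT2 stood at -6.10 (SE 0.29) and SIT1 at -3.25 (SE 0.11). Ribosomal protein genes were higher in E85Q, 119 up and 1 down in mRNA (121 and 1 adjusted over the list alone; 1.89) and 108 up and 2 down in footprints (110 and 2; 1.26). RPL24A rose by 2.71 (SE 0.22), RPL21A by 2.52 (SE 0.24) and RPL9A by 2.56 (SE 0.24) in mRNA, and RPS20 by 2.29 (SE 0.28) and RPS2 by 2.28 (SE 0.30) in footprints. The biotin synthase gene BIO2 rose by 2.05 (SE 0.10) in footprints. Respiratory genes had 40 rises and 1 fall in mRNA (0.84) and 27 and 1 in footprints (28 and 1; 0.53), with SDH2 up by 1.94 (SE 0.08) and 1.52 (SE 0.10). Glycolytic genes had 14 rises and 1 fall (0.60), ADH1 rising by 1.55 (SE 0.10) and PDC6 standing at -1.83 (SE 0.17), and autophagy genes had 25 falls (-0.41), with ATG9 at -1.24 (SE 0.09). Camera adjusted p lay between 1.5e-49 and 0.00012 in mRNA and between 8.5e-23 and 1.5e-10 in footprints, or adjusted p = 0.173 to 0.648 with an estimated correlation.

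TE in starved E85Q cells was lower than in WT for ribosomal protein genes, with 72 falls and 1 rise (84 and 1 adjusted over the list alone; -0.65), RPS26B at -1.27 (SE 0.12) and RPS26A at -0.99 (SE 0.09). Respiratory genes had 19 falls (23 falls and 1 rise; -0.32), COX4 at -0.73 (SE 0.10), and oxidative defence genes 11 falls and 2 rises (-0.33), with HYR1 at -0.63 (SE 0.10). Camera adjusted p was 2.7e-23, 7.5e-08 and 0.00017, or adjusted p = 0.455 to 0.494 with an estimated correlation. The glutaredoxin gene GRX4 was higher in TE by 2.72 (SE 0.15) and ECM32 by 2.59 (SE 0.11). DIM1 TE was lower (-0.41, SE 0.09, adjusted p = 0.0075), a call lost without WT 172 or E85Q 625, and DIM1 footprints stood at -0.34 (SE 0.12, adjusted p = 0.037), a call lost without WT 172, E85Q 623 or E85Q 625, without a filter and on centring (-0.22). In mRNA 2989 genes passed, 767 up and 2222 down, 278 of them at least 2-fold (158 up, 120 down); the median gene stood at -0.17 and centring gave 1502 up and 1281 down. Footprints gave 2599, 1008 up and 1591 down (1542 and 1104 centred). TE gave 1763, 1175 up and 588 down (866 and 807 centred), with 1103 without WT 172 and 733 without E85Q 625.

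Whether E85Q responds differently from WT was tested as the difference of the starvation responses. Ribosomal protein genes fell less in E85Q: 113 of 126 had a positive difference in mRNA and none a negative (117 adjusted over the list alone; relative median 1.94). They were led by RPS9A at 3.57 (SE 0.35), RPS22B at 2.99 (SE 0.35), RPS13 at 2.45 (SE 0.30) and RPS15 at 2.17 (SE 0.25). Part of the difference of RPS9A and RPS22B came from lower mRNA in E85Q with methionine (-1.69 and -1.50). Iron genes rose less, with 20 of 21 negative (-1.14): FIT2 stood at -4.58 (SE 0.16), FIT3 at -4.21 (SE 0.19) and MRS4 at -2.08 (SE 0.08), and outside the list LSO1 at -4.28 (SE 0.52) and FRE5 at -4.05 (SE 0.27). Positive differences prevailed for respiratory genes (33 and none negative, 34 adjusted over the list alone; 0.88), Gcn4 genes (33 and 3, 34 and 3; 0.98), glycolytic genes (15 and 1; 0.95) and synthetases (15 and none; 0.79). Examples were ACO1 at 1.94 (SE 0.12), LYS9 at 1.29 (SE 0.19), ADH1 at 1.91 (SE 0.14) and THS1 at 0.71 (SE 0.12). The Gcn4 and glycolytic lists were already lower in E85Q with methionine, which adds to their positive differences. Small-subunit assembly was already higher there, which adds to its negative difference given below. The leucine pathway gene LEU1 stood at 2.66 (SE 0.16). Sulfate assimilation had 7 positive and 3 negative (0.49), MET17 at 1.11 (SE 0.12) and MET2 at -0.72 (SE 0.10). MET17 mRNA was already lower in E85Q with methionine, which adds to its positive difference. Autophagy had 19 negative (-0.39), ATG9 at -1.16 (SE 0.13), and small-subunit assembly 31 (-0.25), PNO1 at -0.79 (SE 0.10), the last list not passing without E85Q 625 with methionine (-0.21). Camera adjusted p was 2.9e-52 for ribosomal proteins, 2e-25 for respiration, 1.7e-15 for Gcn4 genes, 4.6e-12 for glycolysis, 2.8e-11 for synthetases, 2.7e-08 for iron, 0.0011 for sulfate, 0.013 for autophagy and 0.028 for small-subunit assembly, or adjusted p = 0.123 to 0.723 with an estimated correlation.

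Footprints gave the same directions for ribosomal protein genes (70 positive and 2 negative, 81 and 2 adjusted over the list alone; relative median 1.19), Gcn4 genes (29 and 2, 32 and 2; 0.90) and iron genes (20 negative, 21 adjusted over the list alone; -0.99). Examples were RPS2 at 2.59 (SE 0.42), RPS20 at 2.55 (SE 0.39), HIS4 at 1.24 (SE 0.21) and FRE1 at -2.53 (SE 0.18). The 60S assembly list had 20 negative (-0.25) and small-subunit assembly 23 (25 adjusted over the list alone; -0.29), RRN3 standing at -2.18 (SE 0.25). Camera adjusted p was 5.4e-20, 2.7e-11, 1.8e-10, 0.0048 and 0.00022 in that order, or adjusted p = 0.458 to 0.601 with an estimated correlation. DIM1 footprints differed by -0.55 (SE 0.17, adjusted p = 0.028), a call lost when any of 7 of the 8 libraries was left out, all but WT 600 without methionine, and on centring (-0.38). In TE ribosomal protein genes had 39 negative and 1 positive (50 and 1 adjusted over the list alone; -0.76), respiratory genes 8 negative (-0.37) and oxidative defence 8 and 1 (10 and 1; -0.42). Camera gave adjusted p = 1.9e-27, 2.4e-09 and 1.3e-05, or adjusted p = 0.273 to 0.451 with an estimated correlation. GRX4 TE differed by 2.40 (SE 0.21) and RPS26B by -1.27 (SE 0.16). In mRNA 2954 genes passed (579 up and 2375 down, or 1342 and 986 centred), with the median gene at -0.28. Footprints gave 2025 (673 and 1352, or 1107 and 774 centred), with a median of -0.13. TE gave 1069 (852 and 217, or 373 and 389 centred), with a median of 0.13, and 676 with an unpaired ratio. The TE count was 688 without WT 172 without methionine, 385 without WT 600 with, 436 without E85Q 623 with and 404 without E85Q 625 without methionine.

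D87E against WT with methionine asks the same of the second variant in growing cells. No gene passed in mRNA with limma (0; 207 at an unadjusted p below 0.05, and 0 by voom); DIM1 stood at 0.08 (SE 0.06, adjusted p = 0.98). In footprints 3 genes passed, all lower in D87E: YIL166C at -2.93 (SE 0.36), FIT3 at -2.69 (SE 0.37) and PDC6 at -2.58 (SE 0.35), each at adjusted p = 0.049. The footprint count was 0 by voom, without a filter and at pseudocount 10, and 5 at pseudocount 0.1. In TE 7 passed, all lower, with PDC6 at -2.71 (SE 0.32), YIL166C at -2.49 (SE 0.35), JLP1 at -2.39 (SE 0.30), FIT3 at -2.39 (SE 0.30) and YCT1 at -2.18 (SE 0.30). Without a filter 4 passed in TE, at pseudocount 10 3, and with an unpaired ratio 2. With methionine PDC6 footprints stood at 37.2 ± 20 RPKM in WT and 4.99 ± 1.19 in D87E. Of the 7 genes 4 (PDC6, YIL166C, JLP1 and YCT1) are among the 20 with the largest mRNA rise on starvation. Subtraction of carried-over footprints, set by the ratios of those 20, left 0 calls in footprints and 0 in TE. Sulfate assimilation genes had no call over all genes and 7 falls adjusted over the list alone in both measures (relative medians -0.56 and -0.45, adjusted p = 6.3e-20 and 9.3e-11, or adjusted p = 0.0892 and 0.374 with an estimated correlation). The footprint count was 7 without WT 172 and 0 without WT 600, D87E 887 or D87E 888, and the TE count 20 without WT 172, 2 without WT 600 and 0 without D87E 888.

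In starved cells few genes were called between D87E and WT. The D87E group without methionine had the largest median SD in mRNA (0.079) and footprints (0.10), and a missing call does not show that a gene was alike. No mRNA passed with limma (0; 402 at an unadjusted p below 0.05, and 0 by voom), nor did any footprint value (0; 778 and 0 by voom), and in TE only YCR087C-A, a gene of unknown function, passed, at -0.88 (SE 0.10, adjusted p = 0.020; 0 by voom). Ribosomal protein mRNA stood 0.32 higher in D87E as a list with no member called (adjusted p = 3.9e-14, or adjusted p = 0.801 with an estimated correlation), with RPL13A at 0.45 (SE 0.17), RPL19A at 0.29 (SE 0.11) and RPL31A at 0.53 (SE 0.20), and RPS24A at -0.54 (SE 0.19). Chaperones stood at -0.30 (adjusted p = 3.6e-10, or adjusted p = 0.801 with an estimated correlation), with SSA2 at -0.69 (SE 0.18). Without D87E 887 the ribosomal protein median was -0.0016 and that of the chaperones -0.08, and neither list kept its call. In footprints chaperones stood at -0.46 (14 falls adjusted over the list alone), 60S assembly at -0.16 (5) and small-subunit assembly at -0.13 (10), with SSA2 at -0.74 (SE 0.18), NOG2 at -0.65 (SE 0.12) and ENP2 at -0.41 (SE 0.07). In TE ribosomal proteins stood at -0.24 (19), 60S assembly at -0.15 (15) and small-subunit assembly at -0.11 (5), with RPL9A at -1.41 (SE 0.31), NOG2 at -0.76 (SE 0.11) and RRP5 at -0.51 (SE 0.12). Camera adjusted p was 6.4e-07, 6.3e-06 and 4.1e-06 in footprints, or adjusted p = 0.863 with an estimated correlation, and 9.2e-07, 9.2e-07 and 2.6e-05 in TE, or adjusted p = 0.997 with an estimated correlation. The footprint calls of both assembly lists were lost without D87E 888 (-0.020 and -0.026), and all 3 TE calls without WT 172 (0.0093, -0.042 and -0.044). The counts were 231 in mRNA without D87E 888, 19, 19 and 527 in footprints without WT 600, D87E 887 and D87E 888, and 74, 0 and 0 in TE without WT 600, WT 172 and D87E 887.

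No gene was called with limma between the starvation responses of D87E and WT: 0 in mRNA (231 at an unadjusted p below 0.05), 0 in footprints (574) and 0 in TE (521), with 0 by voom in each. The ribosomal protein list differed by 0.30 in mRNA (adjusted p = 3.7e-09, or adjusted p = 0.942 with an estimated correlation), and by -0.03 without D87E 887 without methionine. The sulfate assimilation list differed by 0.65 in footprints (adjusted p = 3.2e-12, or adjusted p = 0.371 with an estimated correlation), with SUL1 at 2.04 (SE 0.60) and MET3 at 1.90 (SE 0.54), neither called (adjusted p = 0.31). SUL1 footprints without methionine were 2143 and 2310 RPKM in WT 172 and 600 and 2119 and 2047 in D87E 887 and 888, while with methionine they were 6.37 and 15.2 against 2.22 and 0.914. After subtraction of carried-over footprints the list stood at 0.22. Without single libraries that lacked methionine the counts were 1 and 12 in mRNA (D87E 887, D87E 888), 11, 3 and 56 in footprints (WT 600, D87E 887, D87E 888) and 23 in TE (WT 600), and without WT 172 with methionine 9 in TE.

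Between the variants, the starvation responses differed for many genes, the E85Q libraries being those of the comparisons with WT. In mRNA FIT2 stood at 4.35 (SE 0.16) in D87E minus E85Q, FIT3 at 3.97 (SE 0.19), FRE5 at 3.84 (SE 0.27) and LSO1 at 3.54 (SE 0.52). Negative values included RPS9A at -3.01 (SE 0.35), RPS22B at -2.69 (SE 0.35), LEU1 at -2.36 (SE 0.16) and the glutamate dehydrogenase gene GDH1 at -2.16 (SE 0.12). Ribosomal protein genes had 106 negative and 1 positive (111 and 1 adjusted over the list alone; -1.62), respiratory genes 30 negative (-0.73), Gcn4 genes 18 and 4 (17 and 4; -0.65) and iron genes 20 positive (0.98). Camera gave adjusted p = 9.9e-50, 3.9e-23, 4.1e-11 and 6.5e-09, or adjusted p = 0.169 to 0.410 with an estimated correlation. In footprints ribosomal protein genes had 61 negative and 2 positive (74 and 2; -1.06) and iron genes 20 positive (21; 0.86), at adjusted p = 2.1e-13 and 6.5e-13, or adjusted p = 0.552 with an estimated correlation. In TE ribosomal protein genes had 14 positive and 2 negative (4 and 2; 0.58) and sulfate genes 5 and 2 (8 and 2; 0.97). Camera gave adjusted p = 2.7e-18 and 4.5e-06, or adjusted p = 0.405 and 0.319 with an estimated correlation, the latter at -0.17 after subtraction of carried-over footprints; GRX4 stood at -2.33 (SE 0.21). The counts were 2819 in mRNA (2330 up, 489 down; 914 and 1212 centred, median gene 0.28), 1717 in footprints (917 and 800; 729 and 1073 centred) and 1828 in TE (219 and 1609; 520 and 506 centred, where 1026 passed, median gene -0.23). Footprint counts were 1078 and 1069 without D87E 887 or 888 with methionine, and TE counts 1147 without E85Q 625 without methionine and 1187 without D87E 888 with methionine.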

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

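The results of this part come from tested differences between the starvation responses of 2 strains, apart from the patterns of carried-over footprints and of genes with opposite changes, which are weighed here because they bear on translational efficiency (TE). All tests of explanations in this part were chosen after the patterns were seen. The bounds for low read numbers and for scaling of genes with opposite changes were set before their values were known, and the others after. The test for induced neighbours was first set as an odds ratio above 1 with p under 0.05, which it missed, and its bounds were rewritten after that result.

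Between E85Q and WT the responses differed for 2954 genes in mRNA, 2025 in footprints and 1069 in TE. In mRNA the largest positive differences were those of RPS9A (3.57), RPS22B (2.99), the dubious frame YBR191W-A (2.77), RPL8A (2.68) and LEU1 (2.66), and the largest negative ones those of COS1 (-6.48, a gene listed at 0 in some libraries), FIT2 (-4.58), LSO1 (-4.28), FIT3 (-4.21) and FRE5 (-4.05). In footprints they were RPS9A (3.34), RPS22B (2.64), RPS2 (2.59), RPS20 (2.55) and RPS31 (2.44), and LSO1 (-4.76), GRE1 (-4.25), FIT2 (-4.24), FIT3 (-3.35) and FRE5 (-3.32), with DIM1 at -0.55. In TE they were COS1 (8.53), GRX4 (2.40), ECM32 (2.31), AAD6 (1.997) and YEL073C (1.80), and the dubious frames YBR191W-A (-4.92) and YDR154C (-3.43), RPS27B (-1.57), RPL8B (-1.41) and RPS26B (-1.27). List medians relative to all genes were 1.94 for ribosomal proteins, 0.98 for Gcn4 genes, 0.95 for glycolysis, 0.88 for respiration, 0.79 for synthetases, 0.49 for sulfate assimilation, -0.25 for small-subunit assembly, -0.39 for autophagy and -1.14 for iron in mRNA. In footprints they were 1.19 for ribosomal proteins, 0.90 for Gcn4 genes, -0.25 for 60S assembly, -0.29 for small-subunit assembly and -0.99 for iron, and in TE -0.76 for ribosomal proteins, -0.37 for respiration and -0.42 for oxidative defence. At a mean RPKM of at least 50 the sulfate assimilation, small-subunit assembly and autophagy lists lost their calls in mRNA, and small-subunit assembly in footprints.

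Between D87E and WT no gene was called by limma (0 in mRNA, footprints and TE, with 231, 574 and 521 at an unadjusted p under 0.05, and 0 by voom). List differences passed at the preset correlation only, 0.30 for ribosomal protein mRNA (adjusted p = 0.942 with an estimated correlation, and -0.030 without D87E 887 without methionine) and 0.65 for sulfate assimilation footprints (adjusted p = 0.371 with an estimated correlation, and 0.22 after subtraction of carried-over footprints). Between D87E and E85Q 2819 genes differed in mRNA, 1717 in footprints and 1828 in TE. In mRNA FIT2 (4.35), FIT3 (3.97), COS1 (3.94), FRE5 (3.84) and LSO1 (3.54) stood highest and RPS9A (-3.01), RPS22B (-2.69), RPS4A (-2.58), LEU1 (-2.36) and GDH1 (-2.16) lowest. In footprints the highest were FIT3 (5.59), FIT2 (5.53), LSO1 (4.84), YIL166C (4.08) and GRE1 (3.86) and the lowest RPS9A (-3.30), RPL9A (-2.90), RPS2 (-2.85), RPS31 (-2.66) and LEU1 (-2.65). In TE the highest were the dubious frames YDR154C (4.45), YBR191W-A (3.38) and YMR173W-A (2.30) with MET3 (2.63) and SUL1 (2.62), and the lowest were COS1 (-5.74), GRX4 (-2.33), ECM32 (-2.31), PDC5 (-2.07) and AAD6 (-2.03). List medians were -1.62 for ribosomal proteins, -0.73 for respiration, -0.65 for Gcn4 genes and 0.98 for iron in mRNA, -1.06 and 0.86 for ribosomal proteins and iron in footprints, and 0.58 and 0.97 for ribosomal proteins and sulfate assimilation in TE. Subtraction of carried-over footprints changed the TE values of MET3 to 0.26, of SUL1 to -0.88 and of the sulfate list to -0.17, none of them called. The value of SUL1 is no test, since SUL1 itself set the ratio subtracted in both E85Q isolates.

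Footprints of the genes most induced by starvation were present in libraries with methionine at levels that differed between the 2 isolates of each strain. Over the 20 genes with the largest mRNA rise, the ratio of footprints with to without methionine was 1.81 times higher in WT 600 than in WT 172 (quartiles 1.56 and 1.97), while the quotient for mRNA was 0.910. In E85Q the quotients were 1.94 (quartiles 1.77 and 2.31) and 1.11, and in D87E 1.47 (quartiles 1.36 and 1.83) and 1.12, with median footprint ratios of 0.194% and 0.132% in D87E 887 and 888, where the median gene had a footprint ratio 0.851 and 0.634 times its mRNA ratio, against 1.71 to 3.39 times in the other isolates. Carry-over of footprints between libraries, which the labels say were pooled after linker ligation, is a candidate explanation. Of the 7 genes called in TE between D87E and WT with methionine by limma, 4 are among the 20. With ratios taken from the other 16, subtraction left 0 calls. Among the WT and D87E isolates this changed only the ratio of D87E 888, from 0.0276% (YIL166C) to 0.0425% (MHT1). It was thus nearly the same subtraction. NIT1 went from -0.79 (SE 0.12) to -0.50 (SE 0.08). PDC6, YIL166C, YCT1, JLP1, FIT3 and GRE1 went to values between -0.76 and -0.16 (SE 0.18 to 0.43). A change in translation of the 7 genes stays open.

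Ribosomal protein genes fell less in E85Q than in WT, by 1.94 in mRNA relative to all genes. A uniformly weaker response is argued against by the 60S assembly list, which fell in both strains and differed by -0.056 (quartiles -0.26 and 0.22). A weaker response of many other lists stays open. Gcn4, glycolytic, respiratory and synthetase genes also had positive differences (0.98, 0.95, 0.88 and 0.79), and iron and autophagy genes rose less (-1.14 and -0.39). The Gcn4 and glycolytic lists were already lower in E85Q with methionine, which adds to their positive differences. Small-subunit assembly went the other way by falling more (-0.25), and sulfate assimilation by rising more (0.49). Part of this came from levels with methionine, where small-subunit assembly mRNA was already higher in E85Q and MET17 mRNA lower. Scaling of whole libraries moves all genes alike, so apart from the pseudocount it drops out of a difference relative to all genes. The gap between the ribosomal protein and 60S assembly lists differed by 1.98 between the responses, against at most 0.50 between 2 isolates of a strain. That gap largely restates the 2 list values and is no separate test. Reads shared between paralogs are argued against by 19 single-copy ribosomal protein genes, at 2.17 (lower quartile 1.90), next to 1.86 for 107 paired genes. An effect of the Dim1 variant may explain the difference but remains a hypothesis from 2 isolates, untested against other differences between these isolates. Between the D87E and WT responses no single gene was called in mRNA by limma (0 genes, 231 at an unadjusted p under 0.05, and 0 by voom).

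In WT 178 genes rose in mRNA and fell in footprints. For low read numbers, the smaller number of footprint reads in the 2 WT libraries with methionine had a median of 1990 (lower quartile 1186). That result decides little, since these genes had passed an RPKM filter and had more footprints with methionine than without. In the 2 WT libraries without methionine the median was 613 (lower quartile 332), with 4 genes under 100, JIP5 among them. The same bounds were applied to these libraries after the first result and with their values known. The values without methionine argue against low read numbers for the set, but not for those 4 genes. RNA read through from an induced neighbour is argued against for the whole set, of which 16 genes (8.99%, 95% interval 5.23% to 14.2%) had such a neighbour, and for those genes it stays open, with an odds ratio of 1.72 (95% interval 0.937 to 2.98, Fisher exact test p = 0.062) against other genes with rising mRNA. Of the 8 genes whose TE fell at least 4-fold, 4 had an induced neighbour, among them JIP5, with NUT2 and then MET16 on one side. The search took the 2 genes on each side, on either strand, with mRNA up at least 8-fold. Read-through into a gene would come from upstream on its own strand. The 8.99% is therefore an upper bound for this search, and neither the odds ratio nor the 4 of 8 genes tests read-through. Scaling may account for most of the set. Only 50 of the 178 were still called up in mRNA and down in footprints after median-centring, a share under the bound set beforehand. The 8 genes whose TE fell at least 4-fold were among the 50. After centring 97 genes were called that way in all and 76 the reverse way (29 before).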

How the results depend on the processing

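The subtraction of carried-over footprints, voom and the crossed isolate block were chosen after the data were seen, and the other alternatives were planned. Where no cause is named for a result that moved, the cause was not tested. A filter at a mean RPKM of at least 50 tests fewer genes (1660). With it, starvation in WT, E85Q and D87E gave 1413, 1346 and 1396 genes in mRNA, 1413, 1318 and 1410 in footprints and 932, 175 and 956 in TE. E85Q against WT gave 363, 128 and 4 (mRNA, footprints, TE) with methionine and 954, 948 and 701 without, D87E against WT without methionine 2 in TE (1 before), the E85Q minus WT response 797, 708 and 343, and the D87E minus E85Q response 687, 722 and 439. After subtraction of carried-over footprints, D87E against WT with methionine gave 0 genes in footprints and 0 in TE, FIT3 stood at 0.044 in footprints (-2.60 before) and 0.52 in TE (-2.12 before) and the sulfate list at -0.028 in TE for E85Q against WT with methionine, and YCT1 at 0.091 in TE for D87E against WT with methionine. SUL1 and the sulfate list then stood at 1.26 and 0.40 in TE in the E85Q response and at -0.88 and -0.17 in TE for D87E minus E85Q. Both SUL1 values follow from the method, since the ratio subtracted in the E85Q isolates was that of SUL1. At pseudocount 0.1, D87E against WT with methionine gave 5 in footprints, E85Q against WT with methionine 2 in TE, and YBR191W-A stood at -1.27 in TE in the D87E response. At pseudocount 10, D87E against WT with methionine gave 0 in footprints and 3 in TE, starvation in E85Q 533 in TE with GTO1 at -0.15, E85Q against WT with methionine 2 in TE and D87E against WT without methionine 0 in TE. Without a filter, D87E against WT gave 0 in footprints and 4 in TE with methionine and 2 in footprints and 0 in TE without, and E85Q against WT with methionine 1 in TE. With voom D87E against WT gave 0 in footprints with methionine and 0 in TE without. With an unpaired ratio, TE counts were 0 for E85Q and 2 for D87E against WT with methionine, 0 for D87E against WT without, and 676 for E85Q minus WT. Median-centring gave 1026 in TE for D87E minus E85Q.

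Leaving out single libraries leaves fewer samples, and the lone sample is assumed to vary like the other groups. Counts in mRNA ranged from 170 to 1229 for E85Q against WT with methionine, from 0 to 231 for D87E against WT without, and from 0 to 12 for D87E minus WT. In footprints they ranged from 40 to 89 for E85Q and from 0 to 7 for D87E against WT with methionine, from 0 to 527 for D87E against WT without, from 0 to 56 for D87E minus WT and from 1069 to 2186 for D87E minus E85Q. In TE they ranged from 96 to 161 for starvation in E85Q, from 0 to 20 for E85Q and from 0 to 20 for D87E against WT with methionine, from 733 to 1558 and from 0 to 74 without, from 385 to 1126 for E85Q minus WT, from 0 to 23 for D87E minus WT and from 1147 to 1801 for D87E minus E85Q. The libraries with the largest effect are named beside each comparison. The ribosomal protein list in mRNA ranged from -0.0016 to 0.70 for D87E against WT without methionine and from -0.030 to 0.68 for D87E minus WT, both lowest without D87E 887 without methionine. In TE it ranged from -0.45 without WT 600 to 0.0093 without WT 172 for D87E against WT without methionine.

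Counts within 1.5 times of the reported ones numbered 29 of 30 on centring, 8 of 30 at the higher filter, 28 of 30 at pseudocount 0.1, 25 of 30 at pseudocount 10, 25 of 30 without a filter, 28 of 30 with voom, 18 of 18 with an isolate block, 6 of 6 with the crossed block, 6 of 10 with an unpaired ratio, 18 of 20 with subtraction and 111 of 156 without a library. Similar counts can hold different genes. On centring, 1565 of the 2954 mRNA calls and 590 of the 1069 TE calls of E85Q minus WT stayed called. For D87E minus E85Q 1403 of 2819 in mRNA and 725 of 1828 in TE did so. The number was 618 of 1396 for E85Q against WT with methionine in mRNA, and 3435 of 4246 for starvation in WT in mRNA. Named genes kept their direction and side of the threshold in 327 of 335 cases on centring, 323 of 335 at pseudocount 0.1 (1 reversed), 317 of 335 at pseudocount 10 (1 reversed), 316 of 335 without a filter and 203 of 203 at the higher filter. The same held for 310 of 319 with voom, 256 of 258 with an isolate block, 86 of 86 with the crossed block, 94 of 112 with an unpaired ratio, 209 of 225 with subtraction (5 reversed) and 1468 of 1616 without a library. Lists did so in 123 of 124 cases on centring, 112 of 124 at the higher filter, 21 of 22 with an unpaired ratio, 58 of 62 with subtraction (3 reversed) and 595 of 604 without a library (3 reversed), and in all cases at both pseudocounts, without a filter, with voom and with both blocks. The 12 list calls lost at the higher filter were 10 of small-subunit assembly (mRNA in WT, E85Q and D87E starvation, E85Q against WT with methionine and E85Q minus WT; footprints in WT and D87E starvation, D87E against WT without methionine and E85Q minus WT; TE in D87E against WT without methionine) and those of sulfate assimilation and autophagy in E85Q minus WT mRNA. Centring ended the call of glycolysis in WT starvation mRNA, and an unpaired ratio that of ribosomal proteins in TE in D87E against WT without methionine. With an estimated inter-gene correlation 123 of the 124 lists described in the comparisons lost their call, and the exception was sulfate assimilation in the E85Q mRNA response. Depth limits genes of low expression, where 3 reads in a 1-kb gene are an RPKM of 0.037 to 0.14.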

Other observations

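Gene lists not described in the comparisons gave these values for starvation of WT in mRNA, as the list median relative to all genes with the camera adjusted p. Purine synthesis genes had 15 falls and 2 rises among 19 (-1.54, adjusted p = 8e-07, or 0.215 with an estimated correlation), with GUA1 at -3.38 (SE 0.14). Elongation and termination factors had 11 falls and 1 rise among 14 (-2.04, adjusted p = 4e-06, or 0.215 with an estimated correlation), with YEF3 at -3.59 (SE 0.14). Cytosolic chaperones had 10 falls and 5 rises among 19 (-0.91, adjusted p = 0.0078, or 0.491 with an estimated correlation), with SSB2 at -3.26 (SE 0.17).

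Other lists did not pass. Sulfur-compound transport and salvage had 12 rises and 6 falls among 19 (4.22, adjusted p = 0.2), sulfur pathway regulators 5 and 1 among 7 (1.74, adjusted p = 0.2), one-carbon metabolism 8 and 3 among 16 (-0.21, mean 0.10, adjusted p = 0.77), and low-sulfur isozymes 3 and 3 among 6 (-0.40, mean 1.13, adjusted p = 0.54). Oxidative defence had 16 and 4 among 23 (0.29, adjusted p = 0.36), the proteasome 23 and none among 33 (-0.14, mean 0.28, adjusted p = 0.28), phospholipid synthesis 11 and 4 among 19 (0.05, adjusted p = 0.54) and thiamine and biotin synthesis 6 and 1 among 8 (0.13, adjusted p = 0.54). Histones had 7 rises among 10 (0.31, adjusted p = 0.36), a-cell genes 6 among 7 (0.21, adjusted p = 0.26), haploid-specific genes 8 and 1 fall among 9 (0.25, adjusted p = 0.2) and auxotrophic markers 2 and 4 falls among 7 (-0.80, mean 0.12, adjusted p = 0.19).

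Alpha-cell genes had too few measured members for a test. In WT with methionine the mating receptor gene STE2 of a cells stood at 243 ± 12 RPKM in mRNA, against 1.38 ± 0.18 for STE3 and 0.601 ± 0.025 for MF(ALPHA)1. The regulator genes MET28 and MET32 rose by 7.87 (SE 0.12) and 7.66 (SE 0.17) in starved WT cells.

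For E85Q against WT with methionine, the lists for checks of ploidy, mating type and markers held called genes. In mRNA haploid-specific genes had 5 rises among 9 (6 adjusted over the list alone; 0.24, adjusted p = 0.019, or 0.243 with an estimated correlation), with SST2 at 0.45 (SE 0.06), FAR1 at 0.52 (SE 0.09) and STE4 at 0.36 (SE 0.06). Auxotrophic markers had 4 falls and 1 rise among 7 (-0.42, adjusted p = 0.00087, or 0.227 with an estimated correlation), with MET17 at -1.03 (SE 0.09), LEU2 at -0.31 (SE 0.07), HIS3 at -0.59 (SE 0.16) and LYS2 at -0.54 (SE 0.15). The a-cell list had 3 rises among 7 and did not pass (0.07, adjusted p = 0.25). In footprints a-cell genes had 1 rise, MFA1 at 0.93 (SE 0.11), and haploid-specific genes 3 (0.09 and 0.14, adjusted p = 0.038 and 0.045, or 0.32 with an estimated correlation). No marker gene was called in footprints by limma over all genes (0), with 3 falls adjusted over the list alone (-0.29, adjusted p = 0.0087, or 0.32 with an estimated correlation).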
